A study of Mus musculus with 5 samples.

How the data were processed

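Per the labels, 5 samples were measured by droplet sequencing of single cells (10x 3' v2 libraries) from the tibialis anterior of C57Bl/6 mice, of which 2 were sequencing runs of day 0 and 1 each came from days 2, 5 and 7 after notexin. The authors name Cell Ranger 2, Seurat 2.3.4, R 3.6.2 and the genome build mm10 in their processing notes, without the role or order of each. The deposited raw tables hold UMI counts per gene and barcode in 4 matrices, 1 per day, with genes listed where at least 3 barcodes had a UMI. The deposited normalized tables hold the natural log of 1 plus 10000 times the count over the cell's total, and this formula on the raw counts gave the same values to within 6.22e-15. The deposited metadata give the mitochondrial share of each cell as a fraction, which stayed under 20% for every kept cell, and a text label for its cell type. Genes are given by symbol only, so no position or annotation version is stated. The 2 day 0 runs share 1 matrix with no column that tells them apart.

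The metadata columns with gene numbers and the injury day were not used, 2 in each of the 4 tables and 8 in all. The injury column reads day 0 in every table, so the day was taken from the sample labels. Numbers of genes per cell were counted from the matrix, with medians of 1597.5, 2470, 939.5 and 1925.5 at days 0, 2, 5 and 7. Barcodes of the raw tables without metadata (14, 21, 13 and 9) were left out of the main values. Of the genes in the fixed lists, Ighm, Mymk, Mymx, Selenop and Trac were not found in the tables. Platelet, glial, smooth muscle, tenocyte and mature muscle cells had no comparison of levels, and NK- or T-like cells had none either, since comparisons were planned for FAPs, endothelial cells, myeloid cells and MuSCs only, and the later ones kept to these.

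The following were fixed before the data were examined: the classes other than the myeloid one, the 15 lists of 208 genes, the 16 marker lists, the comparisons of days 2, 5 and 7 with day 0 within a class of at least 100 cells, and most alternatives. FAP, endothelial, MuSC and immune classes were taken from the authors' labels. Immune-labelled cells of each day were clustered again with scanpy 1.11.5 (2000 variable genes, 20 principal components, 15 neighbours, Leiden resolution 0.3 with igraph 0.11.9). A cluster was named when at least 3 markers of a type stood 2-fold above the non-immune cells of that day, with 20 counts per 1000000 UMIs (cpm) added to both sides, and at least 1 of them was among its 10 leading genes, with no other type having more there. Clusters without such a name (50, 62, 36 and 29 cells) stayed unnamed. Macrophage-like and dendritic-like clusters together made the myeloid class.

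Several choices were made after the data were seen. A finer resolution was tried before 0.3, clusters were at first set against all other cells of the day, and the rules on the 10 leading genes were added. Macrophage-like clusters alone were the main class before the myeloid class took their place, since 1 kind of cell fell under different names at different days. The filter on list members was set to follow each alternative's own counts. The test of an upper limit on genes took the place of an earlier form that only counted the left-out barcodes with muscle genes. Comparisons of classes with at least 40 cells (endothelial cells at day 2, and MuSCs at days 2, 5 and 7 against each other) and the 5 other added alternatives also came after.

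Within a class, UMI counts were summed over cells and expressed in cpm, and the log2 ratio to the reference day was taken with a 95% interval from the exact binomial split of the 2 counts (Clopper-Pearson, scipy 1.17.1). Where 1 day had 0 counts, a floor of 3 counts took their place, and fold values given as at least are lower bounds from it. In a shallow class this floor can exceed the level at the other day. A list member with 0 counts can then stand as higher. Day 5 endothelial cells held 172583 UMIs against 3103113 at day 0, and day 5 MuSCs 127030 against 1742166 at day 2. How many members this touched was not counted. A list median covers members with at least 20 UMIs over both days, and its interval comes from 1000 Poisson redraws of the counts. A member counts as higher or lower beyond 2-fold. Each list median was also ranked among 10000 random lists matched on expression in 20 bins. Genes named outside the lists were the 3 with the largest and the 3 with the smallest ratios among genes with at least 100 cpm and 50 UMIs at the higher day. Their level also had to be at least 0.5 times that of the highest other class with at least 100 cells that day. Shares carry Clopper-Pearson intervals, and a share of 0 carries the limit of 3 counts instead. For shares of cells with a UMI, cells were thinned at random (seed 1) to 1000 UMIs, and shallower cells were left out. With 1 library per day no test between days was possible.

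Totals per matrix ran from 5986701 to 57723171 UMIs. The method was tested on simulated data with 200 changed genes per comparison, where the sign was right in 100% of genes and the 95% intervals held the true ratio in 88.9% to 97.0% of them. Genes without a change were covered in 96.5% to 97.5%. The simulated counts were Poisson draws, as the intervals assume, and these genes had at least 100 expected UMIs. Genes with few counts and variation between cells or mice were thus not tested. The 18 alternatives covered edgeR 4.0.16 TMM factors, equal weights for cells, the authors' normalized values, thinning to 1000 or 2000 UMIs or none, removal of cells called as doublets by Scrublet (expected rate 5%), minimum depths and counts, other denominators, cell types from fixed markers and other class definitions. With the authors' normalized values, the ratio was replaced by the difference of the cells' mean log values, converted to log2. Scrublet called 76, 10, 5 and 120 cells at days 0, 2, 5 and 7. Computations used Python 3.11.15, numpy 2.4.6, pandas 2.3.3, anndata 0.12.19, scikit-learn 1.9.0 and R 4.3.3, and plots matplotlib 3.10.9.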

Results

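The series sampled the tibialis anterior, a shin muscle, of C57Bl/6 mice without injury and 2, 5 and 7 days after notexin, a snake venom toxin that destroys muscle fibres. Live cells were sorted by dye staining after the muscle was digested and red cells were lysed, and their mRNA was counted with droplet libraries that tag each molecule (UMI). There was 1 library matrix per day, with 5176, 4903, 2164 and 5680 annotated cells and 22330278, 57723171, 5986701 and 40427212 UMIs. The median UMI counts per cell were 3832.5, 9683, 2018 and 5991. The day 0 matrix pooled 2 sequencing runs whose cells cannot be told apart. Mice were 4 months old and female, except 7 months at day 2 and male at day 7, so day cannot be separated from age or sex. Xist, the female X inactivation RNA, stood at 641, 590 and 821 counts per 1000000 UMIs (cpm) at days 0, 2 and 5 and at 0.272 at day 7, where the Y-linked Ddx3y stood at 49.3. No difference between days has a replicate or a test. Values in brackets after a value are 95% intervals (Clopper-Pearson for shares and single genes), and these, like the floors for counts of 0, cover counting error only.

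The first question was which cell types the muscle yielded on each day. Fibro-adipogenic progenitors (FAPs), the collagen-producing stromal cells of muscle, made up 67.9% (66.6 to 69.2) of the cells at day 0, 13.6% (12.7 to 14.6) at day 2, 38.3% (36.2 to 40.3) at day 5 and 33.3% (32.0 to 34.5) at day 7. Endothelial cells made up 21.0% (19.9 to 22.2), 1.18% (0.899 to 1.53), 4.62% (3.78 to 5.59) and 9.15% (8.42 to 9.93). Immune-labelled cells were 5.74% (5.12 to 6.41) at day 0 and 84.0% (83.0 to 85.0) at day 2, then 52.4% (50.3 to 54.5) and 48.1% (46.8 to 49.4). A high immune share lowers the share of every other class. Among non-immune cells alone, FAPs were 72.1% at day 0 and 85.2% at day 2, so their order turned. Endothelial cells were 22.3% and 7.41% on that base and kept theirs. Muscle stem cells and progenitors (MuSCs) had no label at day 0 and made up 1.18% (0.899 to 1.53), 1.85% (1.32 to 2.51) and 6.97% (6.32 to 7.67) later. A missing label does not show that such cells were absent, and fixed markers assigned 0.270% (0.148 to 0.453) of the day 0 cells to MuSCs.

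Among the immune-labelled cells, clusters led by macrophage or dendritic genes (together myeloid) held 3.59% (3.10 to 4.14) of all cells at day 0, 82.8% (81.7 to 83.8) at day 2, 20.5% (18.8 to 22.2) at day 5 and 41.2% (40 to 42.5) at day 7. Clusters led by genes of natural killer (NK) or T cells, such as the cytotoxic granule gene Nkg7 and the T cell receptor chain gene Cd3d, held 42, 0, 655 and 359 cells. Their share was 30.3% (28.3 to 32.3) at day 5 and 6.32% (5.70 to 6.98) at day 7. A cluster led by the neutrophil genes S100a8 and S100a9 appeared at day 0 alone, with 19 cells, and also carried mast cell genes such as Cpa3. Tenocytes, the cells of tendon, were labelled at day 0 (70 cells) and day 7 (88), and mature muscle at day 5 (62) and day 7 (56). Smooth muscle (76 cells), glial (71) and platelet (57) labels occurred at day 0 alone. Cells under the glial label also carried mature muscle markers, at a mean of 6272 cpm against 602 for glial markers. Digestion and the live sort can set these shares, and assignment from fixed markers in place of the labels gave MuSC shares of 0.270%, 0.612%, 0.924% and 3.10%.

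**Figure D1:**
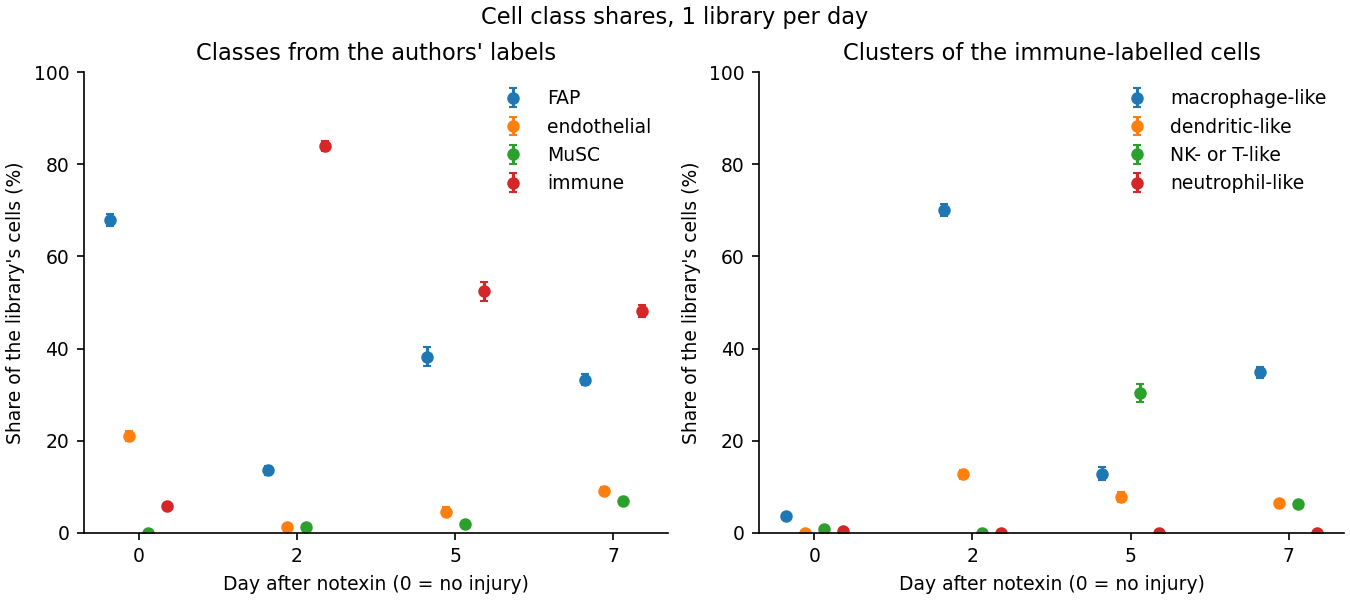
Share of each library's cells (%, y axis) by day after notexin (x axis), for classes from the authors' labels (left) and clusters of the immune-labelled cells (right), with points for the share and bars for the 95% binomial interval. Immune-labelled cells stand at 84.0% at day 2 and FAPs at 67.9% at day 0.

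Whether FAPs differed early after injury was read from day 2 (667 cells) against day 0 (3516 cells). Day 2 FAPs held more mRNA of cell division and matrix genes and less of resting stromal genes. The cell cycle list had a median log2 ratio of 3.21 (2.99 to 3.49), with 15 of 20 measured members at least 2-fold higher and 0 lower. Birc5, which encodes the mitotic protein survivin, stood at 5.66 (5.06 to 6.33) and Ube2c, an enzyme of mitotic exit, at 4.68 (4.13 to 5.29). The extracellular matrix list stood at 1.28 (1.26 to 1.29), with 13 higher and 0 lower of 18. Its largest ratios were 6.67 (5.96 to 7.48) for Tnc (tenascin C), 4.30 (4.19 to 4.41) for the protease inhibitor gene Timp1 and 3.91 (3.78 to 4.05) for Lox, a collagen crosslinking enzyme. The resting stroma list stood at -1.92 (-2.01 to -1.90), with 0 higher and 11 lower of 15, led by Pi16, a marker of progenitor-like fibroblasts, at -4.42 (-4.51 to -4.34). Myoc (myocilin) stood at -4.28 (-4.36 to -4.20) and Gsn (the actin-severing protein gelsolin) at -4.28 (-4.30 to -4.26).

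An expression filter kept genes with at least 100 cpm and 50 UMIs at the higher day and at least 0.5 times the level of the highest other class of at least 100 cells. Among genes past it, the largest day 2 ratios in FAPs were 7.96 (6.98 to 9.18) for Hp, the haemoglobin-binding haptoglobin, 6.61 (6.03 to 7.26) for Nt5dc2 and 5.79 (5.53 to 6.08) for Cthrc1, a secreted protein of activated fibroblasts. The smallest were -5.63 (-6.18 to -5.12) for Inmt, a methyltransferase, and those of Pi16 and Myoc. The stromal chemokine and cytokine list had a median of -0.16 (-0.26 to -0.057), or 0.19 with the authors' normalized values. Its mean was 0.032, and its members went both ways, with Cxcl5, a neutrophil attractant, at 5.01 (4.27 to 5.87) and the eosinophil attractant Ccl11 at -2.05 (-2.10 to -2.0). The interferon response list stood at -0.039 (-0.32 to 0.015), with 0 higher and 4 lower of 13. The dissociation stress list, genes that tissue digestion induces, stood at -0.94 (-1.0 to -0.90), with Junb at -1.79 (-1.82 to -1.76) and the heat shock gene Hspa1a at -1.79 (-1.84 to -1.73). The glycolysis and hypoxia list stood at -0.54 (-0.61 to -0.38), with the growth factor gene Vegfa at -2.25 (-2.53 to -1.98). With the authors' normalized values, the cell cycle and resting medians were 0.11 and -0.76. Values from this setting, here and throughout, are differences of mean log values and not log2 ratios of summed counts. Their size therefore cannot be set beside that of the main values. The median over all genes was -0.17, and relative to it the cell cycle, matrix and resting lists stood at 3.39, 1.45 and -1.75.

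At day 5 (828 cells), FAPs held more mRNA of matrix and interferon response genes than at day 0. The matrix list stood at 1.92 (1.89 to 1.94), with 12 of 18 measured members at least 2-fold higher and 0 lower, and Tnc at 7.72 (7.01 to 8.54) and Postn (the matrix protein periostin) at 4.32 (4.24 to 4.39). The interferon response list stood at 1.47 (1.35 to 1.64), with 10 higher and 0 lower of 13. Its largest ratios were 3.44 (3.06 to 3.82) for the antiviral gene Rsad2, 2.62 (2.43 to 2.81) for Ifit1 and 2.51 (2.38 to 2.65) for Isg15, a ubiquitin-like protein. Cxcl10, a T cell attractant, stood at 1.98 (1.86 to 2.09). The resting stroma list stood at -0.78 (-0.88 to -0.63), with Gsn at -2.08 (-2.10 to -2.06) and Hsd11b1, a glucocorticoid-activating enzyme, at -1.92 (-2.16 to -1.69). Cell cycle genes stood at 0.12 (-0.14 to 0.42), with 3 higher and 2 lower of 17, among them Ccna2 (cyclin A2) at 1.85 (0.46 to 3.16) from 9 counts at day 5.

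Past the same filter at day 5, the largest FAP ratios after that of Tnc were 5.62 (5.34 to 5.91) for Cthrc1 and 4.32 (4.18 to 4.45) for the imprinted RNA H19. The smallest were -3.01 (-3.35 to -2.68) for Fdps, an enzyme of isoprenoid synthesis, -2.60 (-2.98 to -2.24) for the zinc finger gene Zfp385a and -2.53 (-2.76 to -2.31) for the membrane protein gene Tmem100. The chemokine list stood at -0.059 (-0.16 to 0.032), with a mean of 0.041, Cxcl5 at 4.13 (3.27 to 5.08) and the monocyte attractant Ccl2 at -1.32 (-1.44 to -1.21). Genes of dissociation stress stood at -0.18 (-0.22 to -0.11), with the heat shock genes Hspa1b at 1.54 (1.44 to 1.64) and Hspa1a at -1.20 (-1.27 to -1.13). Glycolysis and hypoxia genes stood at -0.64 (-0.81 to -0.54), with the hypoxia regulator Hif1a at 1.69 (1.52 to 1.85) and the glycolytic enzyme gene Aldoa at -1.59 (-1.73 to -1.45). With the authors' normalized values the matrix median at day 5 was 0.82 and the interferon response median 0.14.

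At day 7 (1889 cells), the same 2 lists stood highest in FAPs. The matrix list stood at 2.01 (1.99 to 2.08), with 14 of 18 measured members at least 2-fold higher and 0 lower, including Tnc at 6.98 (6.28 to 7.79), Postn at 5.13 (5.06 to 5.20) and Timp1 at 3.07 (2.96 to 3.18). The interferon response list stood at 2.13 (1.96 to 2.32), with 11 higher and 0 lower of 13, led by Ifit1 at 3.12 (2.97 to 3.27), Rsad2 at 3.04 (2.72 to 3.38) and the transcription factor gene Irf7 at 3.0 (2.83 to 3.16). The resting stroma list stood at -0.77 (-0.78 to -0.76), with 0 higher and 6 lower of 15, Myoc at -3.90 (-3.96 to -3.84) and Gsn at -3.14 (-3.15 to -3.13). The chemokine list stood at -0.95 (-0.97 to -0.93), with 1 higher and 6 lower of 13, Cxcl5 at 2.70 (1.90 to 3.6) and the cytokine gene Lif at -2.06 (-2.74 to -1.43). The cell cycle list stood at 0.39 (0.048 to 0.61), with 4 higher and 1 lower of 20, Cdk1, the mitotic kinase, at 2.96 (2.36 to 3.62) and Birc5 at 1.81 (1.11 to 2.55).

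Among genes past the filter at day 7, the largest FAP ratios were 7.18 (6.37 to 8.14) for Ly6h, 7.10 (6.84 to 7.38) for Cthrc1 and that of Tnc. The smallest were those of Myoc, -3.78 (-3.98 to -3.58) for Fdps and -3.28 (-3.47 to -3.09) for the lipase gene Daglb, which stood at 132 cpm in another class. Dissociation stress genes stood at -0.53 (-0.56 to -0.49), with Hspa1b at -1.47 (-1.59 to -1.35). Glycolysis and hypoxia genes stood at -0.64 (-0.73 to -0.59), with the glucose transporter gene Slc2a1 at -2.42 (-2.78 to -2.08) and Vegfa at -2.14 (-2.36 to -1.93). Among 10000 random lists matched on expression, which are no test between days, the matrix medians at days 2, 5 and 7 ranked at percentiles 100, 100 and 100 and the interferon response medians at 67.1, 100 and 100. The matrix median was 1.37 with the authors' normalized values, and the interferon response median 0.58. RNA of Lyz2, C1qa, C1qb and Apoe, genes of macrophages, stood in FAPs at a median of 6.31%, 0.822% and 2.65% of the macrophage level at days 2, 5 and 7. Tenocyte markers had means of 23.4, 64.1, 186 and 184 cpm in the authors' label FAPs at days 0, 2, 5 and 7. Their medians were 14.8, 30.7, 45.3 and 22.0 cpm, and days 2 and 5 had no tenocyte label.

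**Figure D2:**
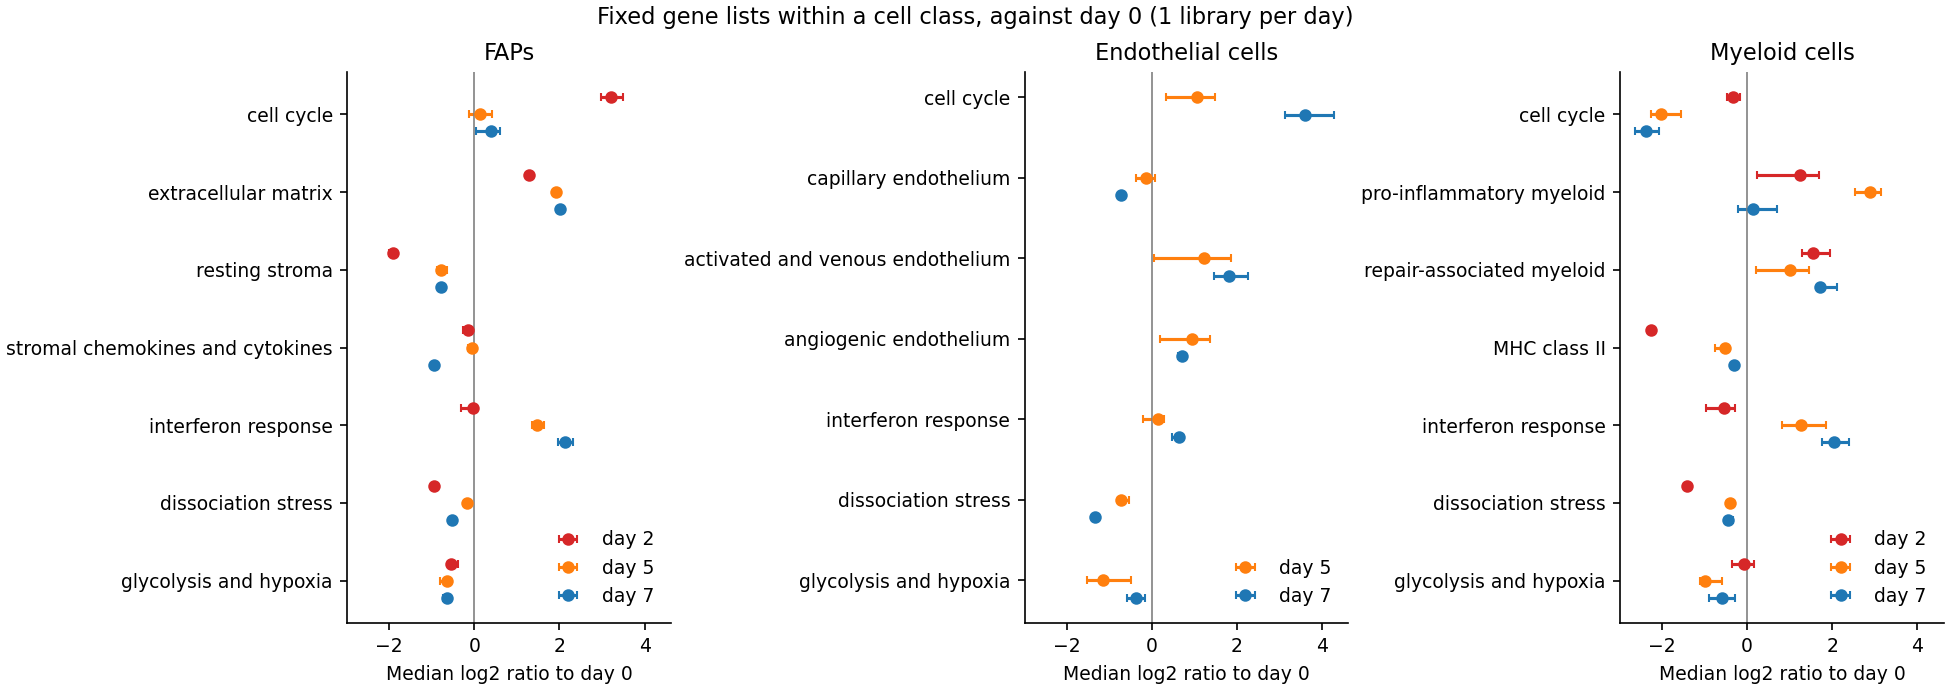
Median log2 ratio to day 0 (x axis) of each fixed gene list (y axis) in FAPs, endothelial cells and myeloid cells, with points coloured by day and bars for the 95% counting interval. In FAPs the matrix list stands at 1.28, 1.92 and 2.01, and in endothelial cells the cell cycle list stands at 3.6 at day 7.

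Endothelial cells at day 5 (100 cells) were compared with day 0 (1089 cells). They held more mRNA of Lrg1, Apln, Col4a1 and Plvap and less of Car4 and Icam1. The activated and venous list stood at 1.23 (0.049 to 1.87), with 3 of 5 measured members at least 2-fold higher and 1 lower, led by Lrg1, a secreted angiogenic glycoprotein, at 3.79 (2.87 to 4.69). The adhesion genes Vcam1 and Icam1 stood at 1.24 (-0.037 to 2.31) and -1.16 (-2.18 to -0.31). The angiogenic list stood at 0.95 (0.19 to 1.36), with 4 higher and 1 lower of 9, including the sprouting peptide gene Apln at 2.52 (1.53 to 3.41), Plvap, a protein of vessel fenestrae, at 2.21 (1.54 to 2.83) and the basement membrane gene Col4a1 at 2.32 (2.17 to 2.46). The capillary list stood at -0.13 (-0.38 to 0.071), with 0 higher and 3 lower of 12, among them Car4, a carbonic anhydrase, at -4.08 (-5.96 to -2.72) and the transcription factor gene Tcf15 at -1.49 (-1.78 to -1.22). Cell cycle genes stood at 1.07 (0.35 to 1.48) over 9 measured members, led by the replication genes Mcm2 at 2.58 (1.22 to 3.79) and Mcm5 at 2.26 (0.93 to 3.42), and stood at 0.24 when cells were thinned to 1000 UMIs. With the authors' normalized values, the venous, angiogenic and capillary medians were 0.032, 0.081 and -0.25.

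Of the genes past the expression filter, the largest day 5 endothelial ratio was 3.54 (3.25 to 3.83) for Col15a1, a basement membrane collagen. Next came 2.39 (2.03 to 2.75) for the adhesion gene Mcam and 2.38 (1.91 to 2.83) for Tnnc2, a troponin of muscle fibres. Tnnc2 stood higher, at 390 cpm, in another class of at least 100 cells. The filter did not cover the 62 cells labelled mature muscle at day 5, whose mature muscle markers, Tnnc2 among them, averaged 16203 cpm. The smallest ratios past the filter were those of the globin genes Hba-a1 at -7.89 (-13.19 to -5.41), Hbb-bt at -6.12 (-11.43 to -3.64) and Hba-a2 at -5.42 (-7.30 to -4.06), genes of red blood cells, from 1 to 4 counts at day 5. Interferon response genes stood at 0.14 (-0.21 to 0.28), with Ifit3 at -1.60 (-3.05 to -0.46) and Ifi27l2a at 1.59 (1.21 to 1.96). Genes of dissociation stress stood at -0.72 (-0.80 to -0.53), with Hspa1b at 2.16 (1.92 to 2.39) and Ier2 at -1.77 (-2.17 to -1.39), and glycolysis and hypoxia genes at -1.15 (-1.52 to -0.48), with Hif1a at 1.97 (1.31 to 2.58). At day 0, RNA of the FAP genes Col1a1, Col3a1, Dcn and Gsn stood in endothelial cells at a median of 12.8% of the FAP level, against 2.37% at day 5.

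At day 7 (520 cells), endothelial cells held more mRNA of cell division genes than at day 0. The cell cycle list stood at 3.6 (3.12 to 4.27), with 19 of 20 measured members at least 2-fold higher and 0 lower. Ccnb2 (cyclin B2) stood at 7.46 (4.96 to 12.77) from 1 count at day 0, Cdk1 at 6.81 (5.25 to 9.10) from 3 counts and Birc5 at 6.79 (5.42 to 8.67). The activated and venous list stood at 1.81 (1.47 to 2.26), with 3 higher and 0 lower of 6, including Selp, the leukocyte-binding P-selectin, at 7.50 (5.00 to 12.81) from 1 count at day 0, and Lrg1 at 4.81 (4.24 to 5.43). The angiogenic list stood at 0.71 (0.61 to 0.81), with Plvap at 3.84 (3.56 to 4.14) and Apln at 2.10 (1.62 to 2.62). The capillary list stood at -0.72 (-0.78 to -0.66), with Car4 at -2.43 (-2.65 to -2.22) and the water channel gene Aqp1 at -1.52 (-1.56 to -1.47).

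Past the expression filter, the largest day 7 endothelial ratio after those of Cdk1 and Lrg1 was 4.28 (3.64 to 4.99) for Fam167b, and the smallest were -8.70 (-10.02 to -7.66) for Hba-a2, -8.52 (-9.52 to -7.68) for Hba-a1 and -8.21 (-10.09 to -6.85) for Hbb-bt, from 4 to 11 counts. Cdk1 stood at 109 cpm in day 7 endothelial cells and higher, at 161 cpm, in another class that day. Interferon response genes stood at 0.64 (0.47 to 0.74), with Cxcl10 at 2.02 (1.73 to 2.32). Dissociation stress genes stood at -1.33 (-1.38 to -1.30), with 0 higher and 13 lower of 18, and Atf3 at -1.79 (-1.94 to -1.64). Glycolysis and hypoxia genes stood at -0.37 (-0.58 to -0.15), with Vegfa at -2.60 (-4.00 to -1.44). With the authors' normalized values they stood at 0.033, and the cell cycle list at 0.22. The median over all genes was -0.11, and relative to it the cell cycle and capillary lists stood at 3.71 and -0.61. Among random lists, the cell cycle medians at days 5 and 7 ranked at percentiles 99.7 and 100 and the capillary medians at 33.6 and 0.270. Macrophage genes stood in endothelial cells at a median of 6.39% of the macrophage level at day 7, against 0.317% at day 0. Called doublets made up 5.96% of endothelial cells at day 7 and 3.58% at day 0.

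Day 2 held 58 endothelial cells, under the planned minimum of 100, and was compared after the data were seen. The activated and venous list stood at 2.36 (1.96 to 2.78), with Selp at 8.09 (5.54 to 13.42) from 1 count at day 0 and Lrg1 at 6.14 (5.56 to 6.78). The capillary list stood at -1.63 (-1.76 to -1.50), with Tcf15 at -2.57 (-2.81 to -2.34), and the interferon response list at -2.08 (-2.49 to -1.49), with Isg15 at -2.82 (-3.27 to -2.40). Cell cycle genes stood at 1.15 (0.48 to 1.35) and the angiogenic list at 0.24 (0.086 to 0.41), with Plvap at 4.09 (3.76 to 4.42). Genes of dissociation stress stood at -0.99 (-1.13 to -0.91) and glycolysis and hypoxia genes at 0.11 (-0.13 to 0.26), with a mean of -0.10. The median over all genes was -0.30, and relative to it the venous and capillary lists stood at 2.65 and -1.34. Macrophage genes stood at a median of 22.6% of the macrophage level in these cells.

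Myeloid cells (186, 4058, 443 and 2343 cells at days 0, 2, 5 and 7) were compared to see how these phagocytes differed after injury. Day 0 held 2 clusters. One, with 110 cells, was led by Retnla, a gene of alternatively activated macrophages, and MHC class II genes, and the other, with 76 cells, by the complement genes C1qa, C1qb and C1qc. A cluster of 136 cells led by Cd74 and Retnla fell among the dendritic-like cells at day 5. Values without the Retnla-led day 0 cluster, a comparison added after the data were seen, are therefore given as well where they moved beyond counting error. They rest on the other 76 day 0 cells, under the planned minimum of 100. The 10 leading genes of those cells include C1qa, C1qb, C1qc and Pf4, members of the repair-associated list, and also Retnla and Cd74. A lower repair-associated ratio can thus follow in part from this choice of reference.

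At day 2, myeloid cells held less mRNA of antigen presentation genes and more of Spp1 and Gpnmb than at day 0. The MHC class II list stood at -2.27 (-2.34 to -2.21), with 0 of 7 measured members at least 2-fold higher and 7 lower, including H2-Eb1 at -3.04 (-3.07 to -3.01) and Cd74 at -2.56 (-2.57 to -2.54). The pro-inflammatory list stood at 1.25 (0.23 to 1.68), with 8 higher and 4 lower of 15, Spp1 (the secreted osteopontin) at 5.74 (5.51 to 5.99) and Chil3, a chitinase-like protein gene with 0 counts at day 0, at least 31.3-fold higher. The repair-associated list stood at 1.55 (1.29 to 1.95), with 13 higher and 2 lower of 19, Gpnmb, a glycoprotein of lipid-laden macrophages, at 4.93 (4.54 to 5.35), Fabp5, a fatty acid carrier, at 4.43 (4.27 to 4.6) and the scavenger receptor gene Cd163 at -4.64 (-4.93 to -4.34). Of genes past the filter, the largest ratios were 6.63 (4.78 to 9.67) for Hal, a histidine-degrading enzyme with 2 counts at day 0, 5.86 (5.11 to 6.73) for Syngr1 and that of Spp1, and the smallest were -9.54 (-9.63 to -9.45) for Retnla, -5.91 (-6.07 to -5.75) for the chemokine gene Ccl17 and -5.49 (-5.69 to -5.30) for the ribonuclease gene Ear2.

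Without the Retnla-led cluster, the day 2 medians were -1.84 for MHC class II, -0.17 for the pro-inflammatory list and -0.067 for the repair-associated list, with -0.49 over all genes, and Ccl17 stood at 0.42. The pro-inflammatory median was -1.45 with the class taken from the authors' labels. With their normalized values it was 0.040, and the repair-associated median 0.36. The cell cycle list stood at -0.33 (-0.47 to -0.17), with Rrm2 at -1.06 (-1.49 to -0.59), but at 1.26 without that cluster and 0.0096 with the authors' normalized values. Interferon response genes stood at -0.54 (-0.97 to -0.29), with Cxcl10 at -2.35 (-2.64 to -2.04), at -1.65 without it and at -0.048 with the normalized values. Dissociation stress genes stood at -1.42 (-1.49 to -1.38), with 0 higher and 14 lower of 18, Egr1 at -2.85 (-3.03 to -2.67) and Hspa1a at -2.33 (-2.37 to -2.28), and at -1.97 without that cluster. Glycolysis and hypoxia genes stood at -0.075 (-0.35 to 0.17), with the vasodilator gene Adm at -4.42 (-5.35 to -3.43). The median over all genes was -0.21, and relative to it the MHC class II list stood at -2.06.

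At day 5, myeloid cells stood higher on the pro-inflammatory and interferon response lists than at day 0. The pro-inflammatory list stood at 2.90 (2.53 to 3.15), with 7 of 11 measured members at least 2-fold higher and 1 lower, led by S100a8 at 5.62 (4.73 to 6.68), the monocyte gene Ly6c2 at 4.86 (2.95 to 7.94) from 2 counts at day 0 and S100a9 at 4.55 (3.65 to 5.63). The list median was 0.30 with the class from the authors' labels and 0.16 with their normalized values. S100a8 and S100a9 stood at -2.64 and -2.82 with the class from the authors' labels, whose day 0 immune label holds the neutrophil-like cluster. The 7 measured neutrophil markers, which include both genes, stood at a mean of 96.6 cpm in the authors' label that held most of these cells at day 5, and all 8 at 5.80 in the same label at day 7. The interferon response list stood at 1.26 (0.82 to 1.85), 0.16 without the Retnla-led cluster and 0.085 with the normalized values, with 8 higher and 0 lower of 13, Irf7 at 2.70 (2.09 to 3.36) and Isg15 at 2.33 (1.96 to 2.73), and Cxcl9, a chemokine gene that interferon gamma induces, was among the largest ratios past the filter at 4.89 (3.64 to 6.53). The repair-associated list stood at 1.01 (0.21 to 1.46), with Gdf15, a stress-induced cytokine, at 4.24 (3.61 to 4.95) and Cd163 at -2.83 (-3.50 to -2.22). The smallest ratios past it were -5.37 (-7.27 to -3.98) for Lmo1, -4.69 (-5.71 to -3.82) for the lectin gene Cd209d and -4.65 (-5.80 to -3.69) for the eosinophil attractant Ccl24. Lmo1 stood at 119 cpm in day 0 myeloid cells and higher, at 137 cpm, in another class that day.

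The day 5 cell cycle list stood at -2.02 (-2.26 to -1.56), with 1 higher and 12 lower of 19 and Cdc20 at -4.82 (-10.18 to -2.21) from 1 count, but at 0.055 when cells were thinned to 1000 UMIs. MHC class II genes stood at -0.51 (-0.77 to -0.48), with H2-DMa at -1.31 (-1.42 to -1.19). Genes of dissociation stress stood at -0.40 (-0.48 to -0.32), with Dnajb1 at -1.25 (-1.53 to -0.98), and glycolysis and hypoxia genes at -0.99 (-1.12 to -0.58), with the glycolytic enzyme gene Eno1 at -1.96 (-2.23 to -1.69). Without the Retnla-led cluster, the medians were 2.3 for the pro-inflammatory list, -0.094 for the repair-associated list, 0.75 for the cell cycle, -0.24 for MHC class II and -0.91 for dissociation stress. The repair-associated median was -0.20 with thinned cells and 0.12 with the authors' normalized values.

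At day 7, interferon response and repair-associated genes stood highest in myeloid cells. The interferon response list stood at 2.04 (1.76 to 2.38), with 10 of 13 measured members at least 2-fold higher and 0 lower, Irf7 at 4.21 (3.64 to 4.83) and Bst2, an antiviral membrane protein gene, at 2.48 (2.27 to 2.70). The repair-associated list stood at 1.71 (1.66 to 2.11), with 14 higher and 3 lower of 19, Gpnmb at 4.86 (4.46 to 5.28), the lipid carrier gene Apoe at 3.53 (3.50 to 3.57) and Cd163 at -5.38 (-5.86 to -4.92). The pro-inflammatory list stood at 0.13 (-0.22 to 0.70), with Ly6c2 at 5.71 (3.85 to 8.75) and Spp1 at 4.66 (4.42 to 4.90). The largest ratios past the filter were 5.82 (4.27 to 8.10) for Il18bp, the interleukin 18 binding protein, from 3 counts at day 0, 4.93 (4.18 to 5.80) for Syngr1 and 4.92 (3.69 to 6.54) for the lectin receptor gene Clec4n. The smallest were -7.07 (-7.14 to -7.01) for Retnla, -6.29 (-6.55 to -6.03) for Ccl17 and that of Cd163.

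The day 7 cell cycle list stood at -2.37 (-2.64 to -2.08), with 0 higher and 14 lower of 20 and the kinetochore gene Cenpf at -4.64 (-5.65 to -3.67). MHC class II genes stood at -0.30 (-0.32 to -0.28), and at 0.040 with each cell weighted equally, 0.065 with the authors' labels and 0.047 with thinned cells. Dissociation stress genes stood at -0.45 (-0.51 to -0.34), with Hspa1b at -2.03 (-2.19 to -1.87), and glycolysis and hypoxia genes at -0.59 (-0.90 to -0.28), with Pgk1 at -2.25 (-2.72 to -1.76). Without the Retnla-led cluster, the interferon response median was 0.88, the repair-associated median 0.29, the cell cycle median -0.56, the MHC class II median -0.029 and the dissociation stress median -0.79, and Ccl17 stood at 0.040. With the authors' normalized values, the interferon response and repair-associated medians were 0.43 and 0.69. The median over all genes was -0.12, and relative to it the interferon response list stood at 2.15. Among random lists, the interferon response medians at days 2, 5 and 7 ranked at percentiles 4.18, 100 and 100 and the repair-associated medians at 100, 100 and 100.

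Which stages of the path from stem cell to muscle the MuSCs held was read from the share of cells with a UMI, each cell thinned to 1000 UMIs. Where no cell had a UMI, a limit of 3 cells is given, which bounds cells with a UMI and not cells that express the gene. Pax7, the transcription factor of muscle stem cells, was seen at day 2 in 0 of 58, which allows up to 5.17%, at day 5 in 9 of 40 (22.5%, 10.8 to 38.5) and at day 7 in 38 of 396 (9.60%, 6.88 to 12.9). Myod1, which commits cells to muscle, was seen in 15 of 58 (25.9%, 15.3 to 39.0), 1 of 40 (2.5%, 0.0633 to 13.2) and 57 of 396 (14.4%, 11.1 to 18.2). Myog, which drives differentiation, was seen in 11 of 58 (19.0%, 9.87 to 31.4); in 0 of 40, which allows up to 7.50%; and in 61 of 396 (15.4%, 12.0 to 19.3). The division marker Mki67 was seen in 4 of 58 (6.90%, 1.91 to 16.7), 1 of 40 (2.5%, 0.0633 to 13.2) and 21 of 396 (5.30%, 3.31 to 7.99).

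In endothelial cells, which should lack the muscle genes, Pax7, Myod1 and Myog were each seen in 0 of 58 cells at day 2, 0 of 100 at day 5 and 1 of 520 (0.192%) at day 7. The day 5 Myod1 share in MuSCs came from 1 cell, and without thinning 3 of 40 cells carried it. Mki67 was seen in 0 of 58, 1 of 100 and 16 of 520 endothelial cells (3.08% at day 7). These cells carried cell cycle mRNA of their own, so their Mki67 shares give no background for MuSCs. Median UMI counts before thinning were 34387, 2524.5 and 5881 in MuSCs and 6688.5, 1433 and 4281 in endothelial cells. Without thinning, 25.9% of day 2 MuSCs carried Pax7 and 89.7% Myod1.

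**Figure D3:**
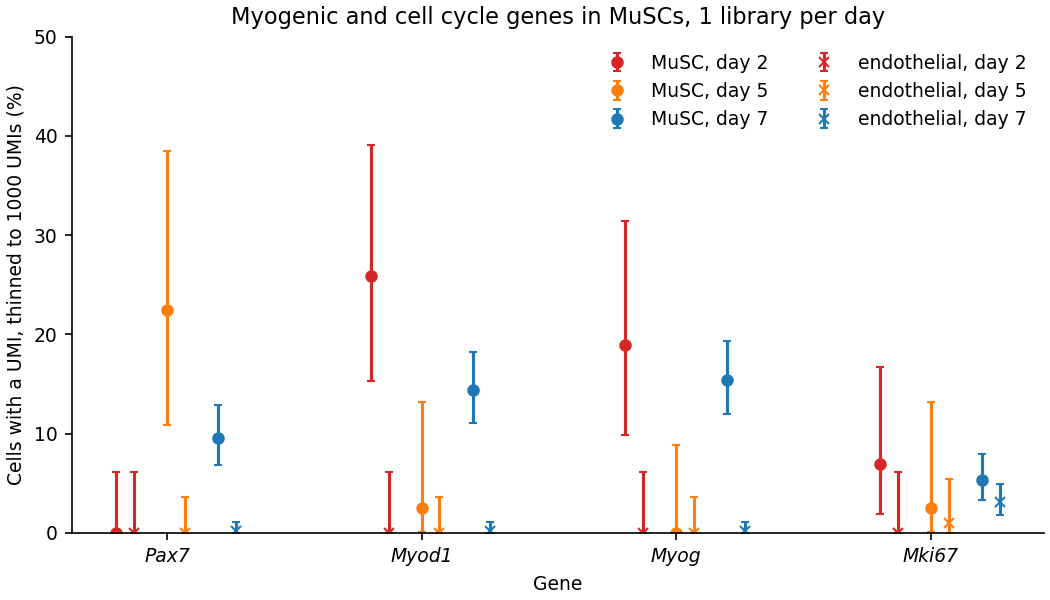
Share of cells with a UMI of each gene (%, y axis) after thinning to 1000 UMIs per cell, for Pax7, Myod1, Myog and Mki67 (x axis) in MuSCs (circles) and endothelial cells (crosses), coloured by day, with bars for the 95% binomial interval. Pax7 stands at 22.5% of MuSCs at day 5 and Myod1 at 25.9% at day 2.

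With 58, 40 and 396 cells and none at day 0, MuSCs met no planned comparison of levels, and these were added after the data were seen. Day 5 MuSCs held more mRNA of quiescence genes than day 2 MuSCs and less of glycolysis and cell cycle genes. The quiescence list stood at 1.75 (1.39 to 2.33), with 7 of 9 measured members at least 2-fold higher and 0 lower, including Heyl, a Notch target, at 4.54 (3.33 to 5.83), the receptor gene Notch3 at 3.93 (3.13 to 4.74) and Pax7 at 3.78 (2.90 to 4.66). The differentiation list stood at -0.86 (-1.10 to -0.35), with 3 higher and 8 lower of 16, Myog at least 16.7-fold lower at 0 counts on day 5 and Myod1 at -3.42 (-5.30 to -2.06). Its higher members were the slow troponin gene Tnnt1 at 1.58 (0.66 to 2.40), Cdkn1c, an inhibitor of the cell cycle, at 1.15 (0.67 to 1.60) and Ckm at 2.01 (0.22 to 3.51) from 5 counts at day 5. Ckm stood higher that day, at 72.9 cpm, in another class of at least 100 cells, and so did Cdkn1c, at 442 cpm. In the 62 cells labelled mature muscle at day 5, Ckm stood at 6117 cpm. Cell cycle genes stood at -1.30 (-1.59 to -0.96), with 0 higher and 14 lower of 20 and the nucleotide synthesis gene Rrm2 at -3.80 (-6.08 to -2.25) from 3 counts. Glycolysis and hypoxia genes stood at -2.37 (-2.99 to -1.95), with 0 higher and 5 lower of 7, Eno1 at -3.30 (-4.30 to -2.46) and Ldha at -3.18 (-4.09 to -2.40). Interferon response genes stood at 1.68 (0.75 to 2.49), but only 5 of the 13 members were measured, with 3 higher and 0 lower. Dissociation stress genes stood at 1.49 (1.41 to 1.80), with Egr1 at 3.67 (3.37 to 3.97).

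Day 7 MuSCs, against day 5, held more mRNA of Myog, Actc1 and Cdkn1c. The differentiation list stood at 0.94 (0.48 to 1.54), with 7 of 15 measured members at least 2-fold higher and 0 lower, Myog at least 35.0-fold higher, the cardiac actin gene Actc1 at 4.91 (2.43 to 10.22) from 1 count at day 5 and Cdkn1c at 2.45 (2.03 to 2.90). The cell cycle list stood at 0.97 (0.76 to 1.23), with 9 higher and 0 lower of 20 and Tyms at 2.65 (0.78 to 5.70) from 2 counts. The quiescence list stood at -0.79 (-1.11 to -0.38), with Calcr at -2.33 (-3.76 to -0.57) and Notch3 at -1.47 (-2.02 to -0.87). Interferon response genes stood at 0.88 (-0.059 to 1.27) and dissociation stress genes at 0.53 (0.29 to 0.72). Glycolysis and hypoxia genes stood at -0.48 (-0.84 to 1.33) over 9 members, with a mean of 0.32. Their median was 1.64 over 5 members with thinned cells and 1.60 over 5 members with at least 100 UMIs.

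Against day 2, day 7 MuSCs stood at 1.91 (1.54 to 2.15) on the quiescence list, with Heyl at 3.75 (2.85 to 4.84) and Pax7 at 2.58 (1.97 to 3.25), and at 4.05 (3.46 to 4.25) on the interferon response list, with 12 higher and 0 lower of 13 and Isg15 at 8.25 (5.77 to 13.56) from 1 count at day 2. The differentiation list stood at 0.38 (0.15 to 0.66), with Cdkn1c at 3.6 (3.43 to 3.77) and the embryonic myosin gene Myh3 at -2.90 (-3.99 to -1.94), but at -0.075 with the authors' normalized values, -0.58 with each cell weighted equally and -0.51 with thinned cells. Cell cycle genes stood at -0.48 (-0.51 to -0.26), dissociation stress genes at 1.99 (1.92 to 2.17) and glycolysis and hypoxia genes at -0.80 (-0.99 to -0.71). The median over all genes was 0.27 here, and relative to it the quiescence and differentiation lists stood at 1.65 and 0.12. With the authors' normalized values, the quiescence medians were 0.41 (day 5 against 2) and 0.23 (day 7 against 2), and the interferon response median 0.26 at day 7 against 2. Pericyte or smooth muscle markers, of which Notch3 is one, had means of 5.17, 67.5 and 147 cpm in MuSCs at days 2, 5 and 7. The day 5 mean covered 7 genes, against 8 at days 2 and 7. These markers rose with the quiescence list from day 2 to day 5 and rose again to day 7. The quiescence list stood at -0.79 for day 7 against day 5, over 11 measured members. Against day 2, however, it stood at 1.75 over 9 members at day 5 and at 1.91 over 11 at day 7. These medians do not settle whether the list fell from day 5 to day 7. Macrophage genes stood in MuSCs at a median of 4.58%, 1.14% and 12.2% of the macrophage level at days 2, 5 and 7.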

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

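The tests of RNA from myeloid cells and of sex at day 5 behind the FAP interferon values, of doublets and of an upper limit on genes behind the day 2 MuSCs, and of the B cell label were chosen only after the result was seen. The depth test was written beforehand.

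Endothelial cells, and also myeloid cells, stood below 0 on the interferon response list at day 2 and above it at day 7. The day 2 median minus the day 7 median was -2.72 in endothelial cells and -2.58 in myeloid cells, and these differences were not tested. The raw tables held 14, 21, 13 and 9 barcodes at days 0, 2, 5 and 7 that the metadata leave out. Those of day 2 held 337 UMIs of Myod1, the muscle commitment gene, which is a signal outside the cells compared above.

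Interferon response genes stood higher in FAPs at days 5 and 7 than at day 0. Against RNA from myeloid cells in the FAP droplets, the 13 interferon genes stood in FAPs at a median of 111% (day 5) and 104% (day 7) of their myeloid level, while the highest of Lyz2, C1qa and C1qb reached 1.42% and 3.13%. For a difference in depth, the list medians with cells thinned to 1000 UMIs were 1.46 and 2.22. Thinning keeps the expected proportions within each cell, so medians near the main ones were likely either way and this test could not decide. Against sex for day 5, the labels give females at days 0 and 5, and the median was 1.47. Depth, sex at day 7 and differences between mice or sorts stay open, and a tissue response to interferon may account for the rest as a hypothesis.

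Day 2 held 58 MuSCs with a median of 34387 UMIs, against 9631 in macrophage-like cells. Against doublets of MuSCs with macrophages, the highest macrophage gene stood in day 2 MuSCs at 6.24% of its macrophage level, where 1 macrophage per droplet would bring 28.0%. All 13 left-out day 2 barcodes with a mitochondrial share under 20% held more genes (6072 or more) than the richest kept cell (5912), and 11 of them carried at least 3 UMIs each of Myod1 and Des, the muscle filament gene. Against an upper limit on genes per cell that removed MuSCs as the source of the low share, counting these 11 as MuSCs gave 1.40% (1.09 to 1.77), where day 7 had 6.97%. Immune-labelled cells made up 84.0% of the day 2 cells, which lowers the share of every other class. Among non-immune cells, MuSCs were 7.41% at day 2, 3.88% at day 5 and 13.4% at day 7, so the day 2 share was not the lowest there. Age, which differed at day 2, and an effect of injury on MuSC number stay open and untested.

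The authors' label B cells held 169 cells at day 2 and 29 at day 5. A UMI of the B cell receptor genes Cd79a and Cd79b or of Ms4a1 (CD20) was seen in 1.78% of them (3 cells) at day 2 and in 0 of 29 at day 5, which allows up to 10.3%. Dendritic markers were seen in 91.7% and 93.1%, against 32.1% and 27.4% of the other immune-labelled cells. These cells may be dendritic cells under another name, as a hypothesis from the markers alone. No biological explanation was tested for this label.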

How the results depend on the processing

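The settings with macrophage-like clusters alone, the authors' myeloid labels, no Retnla-led day 0 cluster, no FAPs (activated) label and the left-out barcodes were chosen only after the data were seen, as were the comparisons of classes with 40 to 99 cells. Over the 18 alternatives, 796 values stayed within counting error, 369 moved beyond it and 21 whose main interval excluded 0 turned. Of the others, 16 medians whose interval reached 0 also changed sign (10 within the error, 6 beyond). The setting with the authors' normalized values changes the measure itself, to differences of mean log values. Under it, 7 of 8 planned medians of the matrix, capillary and repair-associated lists and 106 of 121 other values moved beyond counting error. The cause was not tested unless stated. Leaving out cells called as doublets turned no value whose interval excluded 0, but few cells were called at days 2 and 5. The day 7 pro-inflammatory myeloid median fell from 0.13 to -0.016 without called doublets. Leaving out cells under 1000 UMIs could change almost nothing. The shallowest kept cells held 1434, 4422, 998 and 2626 UMIs at days 0, 2, 5 and 7. All 24 planned and 121 other values of this setting stayed within counting error for that reason and are no check. No paired analysis was possible because the labels pair no samples across days. The alternatives without day 0 replicate 1 and without day 0 replicate 2 were not run, since the matrix does not tell the runs apart. With TMM factors, the median over all genes moved by over 0.1 in FAPs at day 2 (to -0.046), endothelial cells at days 2 and 7 (-0.12 and -0.0014), myeloid cells at days 2 and 7 (0.068 and 0.11) and MuSCs (-0.45 for day 5 against 2, 0.11 for 7 against 5, -0.016 for 7 against 2), and without the Retnla-led cluster in myeloid cells at days 2 and 7 (-0.49 and -0.34). Thinning moved it in day 2 endothelial cells (-0.017) and MuSCs (-0.46, 0.26 and 0.10), the authors' labels in day 7 myeloid cells (-0.22), and the normalized values in the contrasts moved by TMM factors other than MuSCs at day 7 against 5, to between -0.16 and 0.041.

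As shares of non-immune cells, FAPs were 72.1, 85.2, 80.4 and 64.1% at days 0, 2, 5 and 7, endothelial cells 22.3, 7.41, 9.71 and 17.6%, and MuSCs 7.41, 3.88 and 13.4% at days 2, 5 and 7, by construction higher. On this base FAPs stood higher at day 2 than at day 0, the reverse of their share of all cells. Shares carry no sign, so such a change was not counted among the values that turned. With cells assigned from fixed markers, FAPs were 70.5, 43.1 and 36.0% at days 0, 5 and 7, MuSCs 0.270, 0.612, 0.924 and 3.10% at days 0, 2, 5 and 7, and immune cells 4.12 and 44.6% at days 0 and 5.

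Without thinning, MuSCs with Pax7 were 25.9, 40 and 36.6% at days 2, 5 and 7, and at days 2 and 7 those with Myod1 were 89.7 and 32.6%, with Myog 43.1 and 21.5% and with Mki67 69.0 and 23.7%, since deeper cells show more genes. Thinned to 2000 UMIs, the day 7 shares were 18.4% for Pax7, 18.7% for Myod1 and 11.4% for Mki67. Cells of day 5 were the shallowest, which limits what their shares and low-count genes can show.

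The FAP matrix medians were 1.41 and 1.88 at days 2 and 5 with TMM factors, 1.35 and 1.70 with equal weights and 1.33 and 1.70 with thinned cells. They were 1.35, 0.82 and 1.37 at days 2, 5 and 7 with the authors' normalized values, and 2.16 at day 7 without FAPs (activated). The stromal chemokine median at day 2 was 0.19 with the normalized values. The endothelial capillary median at day 7 was -0.61 with TMM factors and -0.52 with the normalized values, which gave 0.033 for glycolysis and hypoxia.

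The repair-associated myeloid medians were 1.12 and 1.30 at days 2 and 7 with equal weights, and at days 2, 5 and 7 were 0.36, 0.12 and 0.69 with the normalized values and 0.68, -0.20 and 1.34 with thinned cells. At day 5 the median was 0.17 with members of at least 100 UMIs, and at day 2 it was 2.04 with the authors' labels. Without the Retnla-led day 0 cluster it was -0.067, -0.094 and 0.29 at days 2, 5 and 7, beside medians over all genes of -0.49, -0.029 and -0.34, so the change at day 2 was in part one of all genes. The 76 day 0 cells then left as reference were led by genes that include members of this list, which can itself lower the ratio. The same setting gave 1.26 and 0.75 for the cell cycle at days 2 and 5, -0.17 for the pro-inflammatory list at day 2, and 0.42 and 0.040 for Ccl17 at days 2 and 7. The cell cycle median was 0.0096 at day 2 with the normalized values and 0.055 at day 5 with thinned cells, over 3 members. With the authors' labels the pro-inflammatory median at day 2 was -1.45, and S100a8 and S100a9 at day 5 stood at -2.64 and -2.82. The day 0 immune label also holds the neutrophil-like, NK- or T-like and unnamed cells, and which of them moved these values was not tested. MHC class II at day 7 was 0.040 with equal weights, 0.047 with thinned cells and 0.065 with the authors' labels. In MuSCs, differentiation genes at day 7 against day 2 stood at -0.58 with equal weights, -0.075 with the normalized values and -0.51 with thinned cells.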

Other observations

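Both tests reported in this part were written before their results were seen, and none was chosen after. Genes named here outside the fixed marker lists were chosen after their values were seen.

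Levels in classes without a comparison are given in counts per 1000000 UMIs (cpm). NK- or T-like cells at days 0, 5 and 7 carried Nkg7 at 2209, 1582 and 2218 and the granzyme gene Gzma at 2556, 2273 and 2088. The T cell gene Cd3d stood at 623, 424 and 583, and the interferon gamma gene Ifng at 584, 145 and 271. Mki67 stood at 0 in the 42 cells of day 0, which allows up to 23.7, and at 68.6 and 113 at days 5 and 7. A day 5 cluster of 51 T-like cells was led by genes that included Il17a, an inflammatory cytokine, and Cd163l1. Dendritic-like cells at days 2, 5 and 7 carried Cd209a, a marker of monocyte-derived dendritic cells, at 760.2, 267 and 508, and Ccr7, the receptor that guides migration to lymph nodes, at 108, 481 and 572. Xcr1, a marker of cross-presenting dendritic cells, stood at 23.4, 19.1 and 75.3 and Flt3, a growth factor receptor of dendritic cells, at 89.8, 146 and 149. Unnamed clusters of 62, 17 and 29 cells at days 2, 5 and 7 were led by Siglech, a marker of plasmacytoid dendritic cells.

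Tenocytes at days 0 and 7 carried the tendon genes Tnmd at 3383 and 3516 and Scx at 371 and 545. Their matrix genes Comp and Fmod stood at 3156 and 13871 at day 0 and at 1459 and 4837 at day 7, and Thbs4 at 6215 and 9952. Cells labelled mature muscle at days 5 and 7 carried the skeletal actin gene Acta1 at 15816 and 48656, the creatine kinase gene Ckm at 6117 and 13758 and the fast myosin gene Myh4 at 832 and 259.5.

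Some labels and markers stood apart. The 57 cells labelled platelets at day 0 held 0 UMIs of the platelet genes Ppbp and Gp9 and 6 of Itga2b (28.3 cpm, against 24.4 in day 0 tenocytes). They held 1023 cpm of Vwf, 1093 of Pecam1 and 28586 of Fabp4, genes of endothelial cells. The 71 cells labelled neural, glial or Schwann cells at day 0 carried mature muscle markers at a mean of 6272 cpm and glial markers at a mean of 602 cpm. The day 5 label of macrophages, antigen-presenting and T cells carried Nkg7 at 1140, Gzma at 708 and Cd3d at 621 cpm.

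A hypothesis was that interferon gamma from NK and T cells lay behind the interferon response values at days 5 and 7. The NK- or T-like class held 88.8% of the Ifng UMIs at day 5 and 78.1% at day 7, against a bound of over 80% set in advance for both days. It also held 85.1% at day 0, the reference day, with 74 of 87 UMIs. Where these UMIs lie therefore could not decide the question, and the hypothesis could be neither kept nor excluded. Another was that single MuSCs sat inside the FAP label at day 0, where no cell was labelled MuSC. UMIs of 2 or more of Pax7, Myf5, Chodl, Chrdl2 and Megf10 were seen in 17 of 3516 FAP-labelled cells, against 0.672 if the genes were independent, a ratio of 25.3, and in 2 of 1089 endothelial cells, against 0.0156, a ratio of 128, so the excess was not limited to the FAP label. Some of these cells may be MuSCs, although doublets of MuSCs with other cells would give such cells too.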
